A study of Mus musculus with 4 samples.

How the data were processed

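Lung tumours of 4 mice were compared, 2 with KrasLA1 and 2 with KrasLA1 and Dicer1S2D, 1 female and 1 male in each group, all aged 55 weeks. Group, replicate number and sex were taken from the labels. Per the labels' protocols, 40-50 mg of dissected tumour was frozen and a company, Active Motif, made, sequenced and analysed the libraries. Whether a sample held 1 tumour or several is not given in the sources used here.

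The deposited table holds 5 tracks of genomic intervals in mm10, per the file headers: 1 of peaks for each library, called separately, and 1 of merged regions. The submitters' processing notes name BWA 0.7.12, MACS3 3.0.0 and deepTools 3.5.1. The role and settings of each, the peak threshold, the filters, any shift of reads for the position of the transposase and the number of reads are not given in the sources used here. Each interval has a chromosome, a start, an end and a name, with no count, score, height or p-value, so the deposited values tell only whether and where a peak was called. A peak that misses an unknown threshold is recorded as absent, and a library with fewer reads can have fewer peaks with the same chromatin, so a region called in 1 group only need not be closed in the other. Signal tracks were not used here. All 5 tracks were assigned, and 0 columns belonged to other samples.

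Peaks of the 4 libraries were merged into regions where they overlapped by 1 bp or more, and the result was equal to the authors' 61972 merged regions. Coordinates are printed counted from 1. A region was gained if called in both KrasLA1;Dicer1S2D libraries and neither KrasLA1 library, and lost in the reverse case, on the 19 autosomes. The same counts were made for the other 2 of the 3 splits of the libraries into 2 and 2, by replicate number and crossed. Presence in 2 against 2 libraries has no replicate test that can reach 0.05, so the other splits show the level that arises without a contrast of genotypes.

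Genes came from a RefSeq gene table for GRCm38.p6, whose primary assembly is that of mm10, with 21887 protein-coding genes placed. It gives neither strand nor exons, so transcription start sites, exons and introns were not annotated, and an end of a gene can be its start or its finish. A region was counted for a gene if it overlapped the gene or lay within 10 kb of it. Each region was classed as within 2 kb of a gene end, otherwise in a gene, within 10 kb, or other.

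The 18 gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 271 list symbols, with a gene of several lists counted in each, 266 were matched, and Gif, Dpcr1, Ela2a, H19 and Meg3 were not, or are not protein-coding. Named genes were up to 4 per list and direction with a gained or lost region, the 10 genes per direction with the most such regions (ties by total width), the 5 widest regions per direction, and Dicer1, Nkx2-1, Hnf4a, Foxa2 and Gata6; 1 further gene fixed in advance is not reported here. Each list was tested per direction with Fisher's exact test, two-sided, against all other protein-coding genes with a region, and p-values were adjusted after Benjamini and Hochberg over the 36 tests of a split. Group means were compared with exact two-sided permutation tests. Shares have 95% Wilson intervals, which cover counting error only. Peak sets were compared by the Jaccard index over base pairs.

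Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used, and limma 3.58.1 in R 4.3.3 for log2 peak width centred on the median of each library. A test for differential regions on counts or signal was planned and not run, because the table holds no value per region. The test of peak width and the geometric mean over both directions of a split were chosen after seeing the data. The permutation tests and limma measure the spread between these mice, and Fisher's exact tests count genes or regions of these 4 libraries and hold no spread between mice.

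The steps were tested on simulated data. All 200 gained and 200 lost regions planted among 60713 were recovered. Their calls were set to the very pattern that the rule selects, so this checks the code and not the sensitivity to real changes. Simulated libraries without a shared pattern gave geometric means of 1255, 1278 and 1299 for the genotype, replicate-number and crossed splits. Random gene lists gave p under 0.05 in 3% of tests over 100 lists, and a planted list reached an adjusted p of 2.02e-09. The test of peak width over 24604 regions recovered 97% of 200 regions changed 4-fold and 13% of those changed 2-fold with an equal spread in every region, and 0% of either with the spread of the libraries.

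Alternatives covered the overlap that merges peaks (shared by at least 50% of the narrower peak, or a gap up to 500 bp), the widest 75% of peaks, equal numbers of widest peaks, X and Y, a minimum width of 200 bp, the assignment of genes, a window of 5 kb at gene ends, a replicate block and each library left out. Width stood in for a score, which the table does not hold.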

Results

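Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 4 samples of snap-frozen lung tumour, 1 from each of 4 mice aged 55 weeks. Whether a sample held 1 tumour or several is not given, and a sample is called a tumour in what follows. All 4 mice carried KrasLA1, a latent oncogenic allele that is activated by spontaneous recombination and gives rise to lung adenocarcinomas. The KrasLA1 group had 2 samples from mice without a further allele named in the labels, and the KrasLA1;Dicer1S2D group had 2 samples from mice that also carried 1 copy of Dicer1S2D, an allele of the microRNA-processing enzyme Dicer1 made to mimic its phosphorylated form. In both groups replicate 1 came from a female and replicate 2 from a male, so replicate number and sex were the same division of the libraries. The values are the positions of the authors' peaks in mm10, called in each library on its own. A peak is therefore present or absent, with no height, score or read count, and the sequencing depth of the libraries is unknown.

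The mean number of open regions differed between genotypes by less than the spread between tumours, which was widest in the KrasLA1;Dicer1S2D group. The authors called 41621 and 44654 peaks in KrasLA1 replicates 1 and 2, and 50282 and 34767 peaks in KrasLA1;Dicer1S2D replicates 1 and 2. The group means were 43137.5 ± 2144.65 peaks (SD, n = 2) in KrasLA1 and 42524.5 ± 10970.8 peaks (SD, n = 2) in KrasLA1;Dicer1S2D, a difference of -613 peaks (exact two-sided permutation test, p = 1). Peaks covered 25.3 ± 3.66 Mb (SD, n = 2) in KrasLA1 and 22.0 ± 4.23 Mb (SD, n = 2) in KrasLA1;Dicer1S2D (exact two-sided permutation test, p = 0.667). The median peak width was 493.5 ± 57.3 bp (SD, n = 2) and 439 ± 41.0 bp (SD, n = 2) in the same order (exact two-sided permutation test, p = 0.667). With 2 libraries against 2, the smallest p this test allows is 0.333. The sign of the difference in peak number rested on single libraries: it was 903.5 without KrasLA1 replicate 2 and 7144.5 without KrasLA1;Dicer1S2D replicate 2, and -8370.5 without KrasLA1;Dicer1S2D replicate 1 and -2129.5 without KrasLA1 replicate 1.

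Proximal Y peaks matched the sex given for each mouse, and X peaks did not separate the sexes. Both male tumours had 6 Y peaks below 90 Mb, between positions 258872 and 11858307, and both female tumours had 0 there. All Y peaks of the female tumours (6 in KrasLA1 and 15 in KrasLA1;Dicer1S2D) lay between positions 90737546 and 90813217, at the distal end of Y. On X the female tumours had 753 (KrasLA1) and 1026 peaks (KrasLA1;Dicer1S2D), 1.81% and 2.04% of their peaks, and the male tumours 938 and 636, 2.10% and 1.83%.

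The first question of the design was which chromatin was open in tumours of only 1 genotype. Few regions followed the genotype in every library: 362 autosomal regions were called in both KrasLA1;Dicer1S2D tumours and neither KrasLA1 tumour (gained), and 861 in both KrasLA1 tumours and neither KrasLA1;Dicer1S2D tumour (lost). Of 60713 autosomal regions, 26402 (43.5%) were called in all 4 libraries and 16827 (27.7%) in 1 library. Gained regions had a median width of 315.5 bp and lost regions of 382 bp, against 789.5 bp for regions called in all 4 libraries. Gained regions touched 283 protein-coding genes (in the gene or within 10 kb of it) and lost regions 773 of the 15882 such genes with a region in any library, and 15 genes had both.

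The genes with the most gained regions had 2 each. They were Fermt1 (kindlin-1, an adaptor that activates integrins), Itgb5 (an integrin beta subunit), Gnaq (a G protein alpha subunit), Syt1 (synaptotagmin, a calcium sensor of vesicle release), Dab1, Slc10a7, Trmo and Macrod2. Genes with many regions have more chances of a gained one: Macrod2 held 38 regions (4 of them called in both replicates 1 only), Gnaq 19, Dab1 and Itgb5 12 each, Slc10a7 8, Syt1 7, and Fermt1 and Trmo 5 each. Tcim and Slc38a1, an amino acid transporter gene, followed with 1 wide region each. The widest gained region, 1151 bp on chromosome 8 from 24437908 to 24439058, overlapped Tcim. It was followed by a region of 1089 bp at an end of Fermt1 (chromosome 2, 132945064 to 132946152), 1 of 1065 bp outside genes and 10234 bp from Topaz1 (chromosome 9, 122735901 to 122736965) and 1 of 1030 bp at an end of Slc38a1 (chromosome 15, 96641230 to 96642259). The fifth, of 940 bp (chromosome 8, 24338777 to 24339716), lay 97456 bp from Tcim. Gnaq also had 1 lost region.

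The genes with the most lost regions had 3 each: Chrm3 (a muscarinic acetylcholine receptor), Kcnj15 (a potassium channel), Nrn1, Nedd9 (a scaffold of adhesion signalling), Cadps2 and Tbx15 (a T-box transcription factor). Spry2, Rcsd1, Hacd2 and Gse1 followed with 2 each. Nedd9 held 22 regions in all, Cadps2 15, Kcnj15 9, Nrn1 6 and Gse1 40. At Tbx15, all 4 regions near the gene were called in both KrasLA1 tumours, 0 in KrasLA1;Dicer1S2D replicate 1 and 1 in KrasLA1;Dicer1S2D replicate 2. At Chrm3, 13 and 12 of 15 regions were called in KrasLA1 replicates 1 and 2, and 3 and 8 in KrasLA1;Dicer1S2D replicates 1 and 2. The widest lost region was 1663 bp at an end of Jag2, a Notch ligand gene (chromosome 12, 112928663 to 112930325). Next came 1280 bp in Sh3pxd2a (chromosome 19, 47314645 to 47315924), 1221 bp at an end of Trim8 (chromosome 19, 46501818 to 46503038), 1213 bp in Hacd2 (chromosome 16, 35033432 to 35034644) and 1194 bp lying 18446 bp from Gm7244 (chromosome 9, 31235163 to 31236356).

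**Figure D1:**
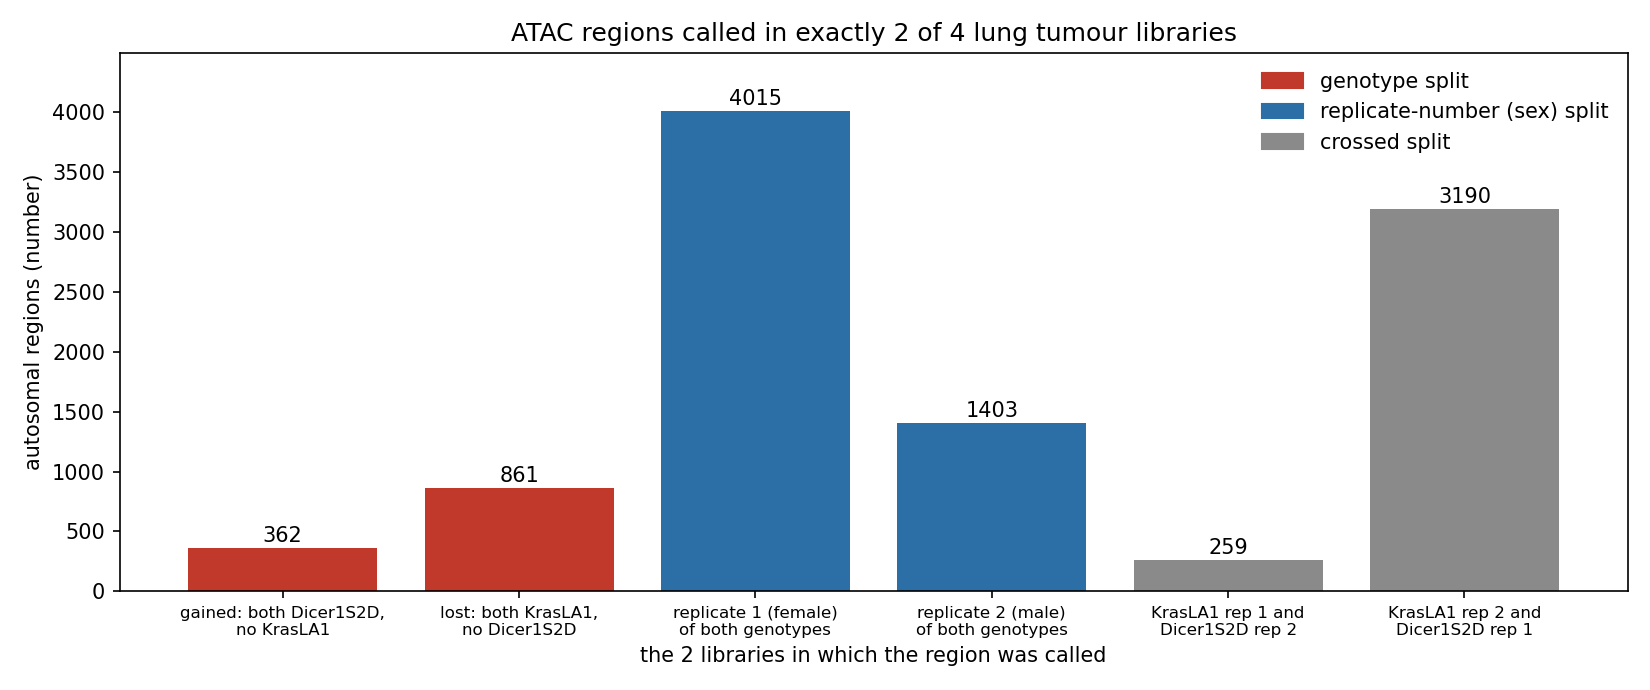
Autosomal regions called in exactly 2 of the 4 libraries, one bar per pair of libraries, with the number of regions on the vertical axis. The 362 gained and 861 lost regions (red) stand beside 4015 and 1403 regions shared by tumours of the same replicate number and sex (blue) and 259 and 3190 regions of the crossed pairs (grey).

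These counts were set beside the other ways of dividing 4 libraries into 2 and 2. Tumours of the same replicate number, and so of the same sex, shared more of these regions than tumours of the same genotype. The genotype split held 1223 of the 10090 regions called in 2 libraries (12.1%, 95% Wilson interval 11.5 to 12.8). The replicate-number split held 5418 (53.7%, 52.7 to 54.7), and the crossed split 3449 (34.2%, 33.3 to 35.1). A library with more peaks fills some pairs more than others. The geometric mean of both directions of a split was 558 regions for genotype, 2373 for replicate number and 909 for the crossed split. It is free of this effect only if each library has 1 call rate that acts alike on all regions. In that case the ratio of gained to lost regions would be the same from regions called in 1, 2 or 3 libraries. The ratio was 0.271, 0.420 and 1.11, so the means may still depend on peak numbers. The intervals cover counting error only.

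The balance of gained and lost regions moved with the number of peaks per library. Gained regions were 29.6% of the gained and lost regions together, and 47.8% (569 gained, 621 lost) when the 34767 widest peaks of each library were used. Leaving out 1 library, which lets fewer libraries decide, gave 1435 gained and 6291 lost regions without KrasLA1 replicate 1, 2809 and 4462 without KrasLA1 replicate 2, 1092 and 4096 without KrasLA1;Dicer1S2D replicate 1, and 7558 and 1577 without KrasLA1;Dicer1S2D replicate 2. Among the named genes there were 41 pairs of a gene and a direction. With only the widest 75% of peaks 17 of these pairs still had such a region, and with equal numbers of peaks 27.

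**Figure D2:**
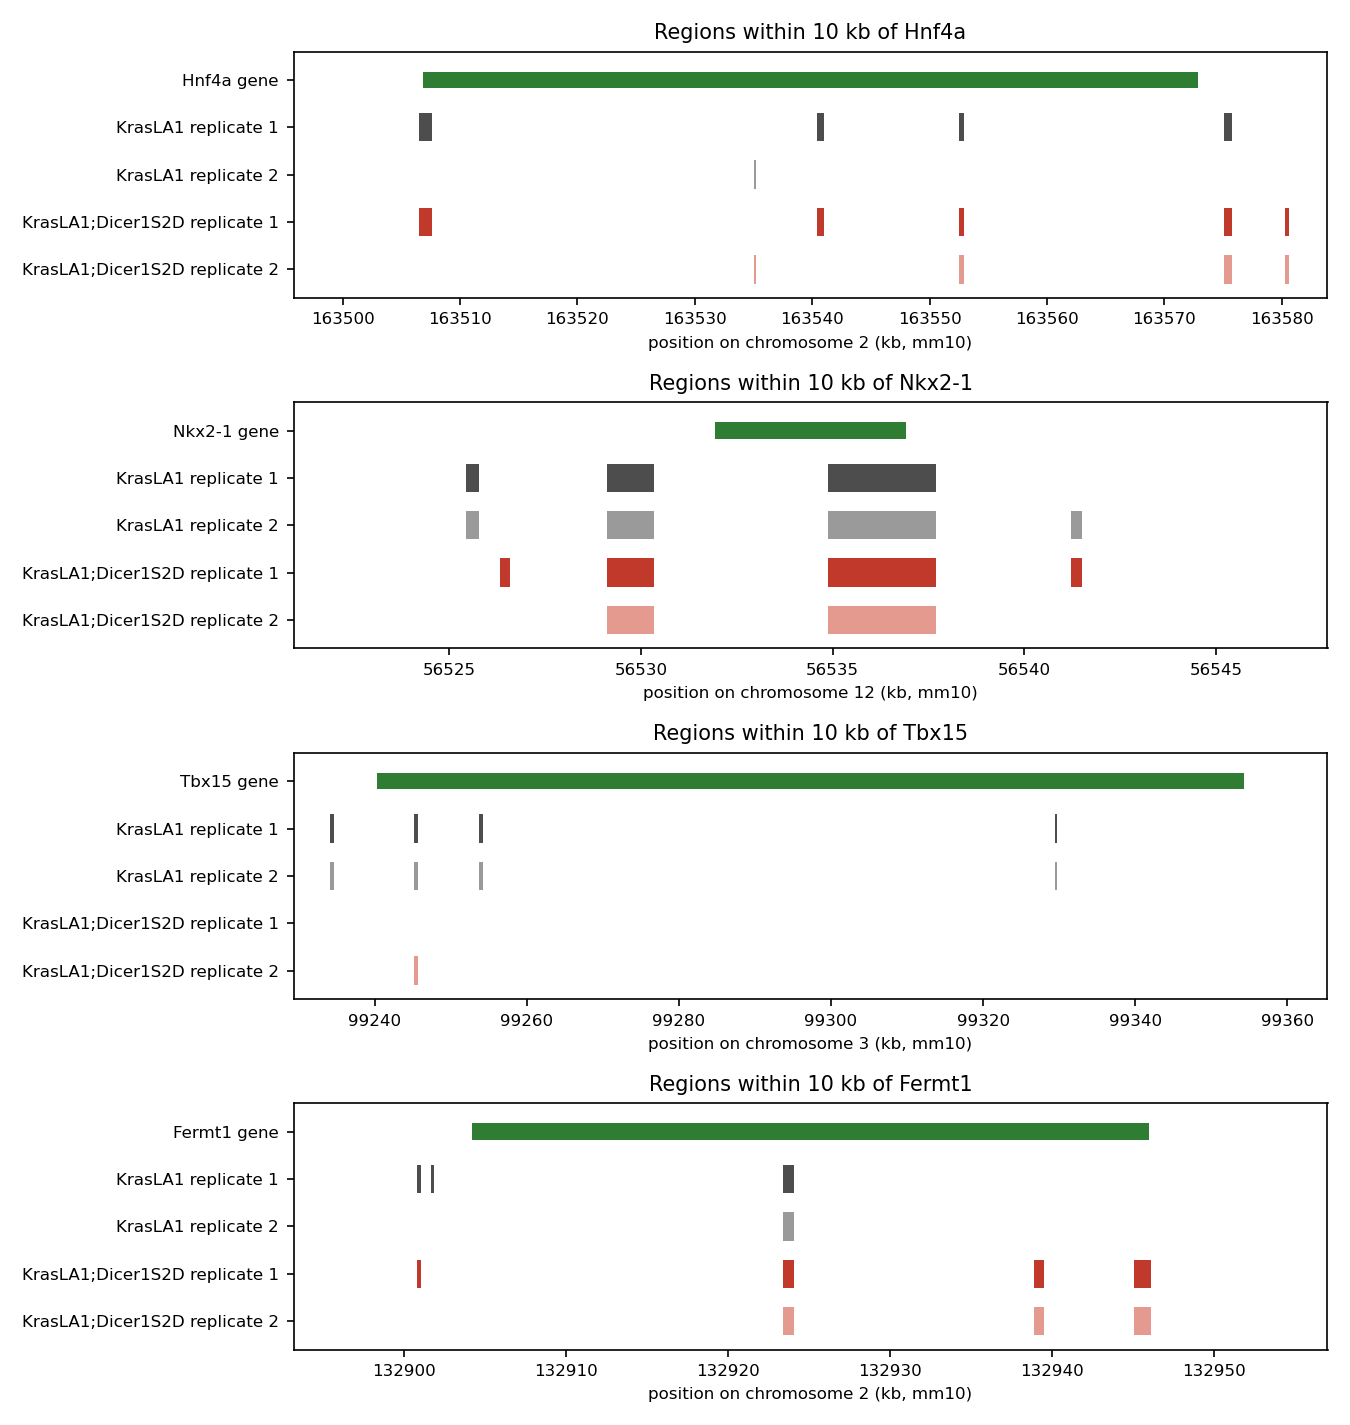
Regions within 10 kb of Hnf4a, Nkx2-1, Tbx15 and Fermt1 by position (kb, mm10), one row per library, with the gene as a green bar. A bar marks the extent of a merged region in each library where a peak was called; 1 region near Hnf4a and 2 at Fermt1 are gained, 1 near Nkx2-1 and 3 at Tbx15 are lost.

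The title of the series names gastric cell fate, and the loci of gastric epithelial genes were examined for it. Of 27 gastric genes with an autosomal region, 2 had a gained region. They were Hnf4a, a transcription factor of gastric, intestinal and liver epithelium, and Atp4a, the catalytic subunit of the proton pump of parietal cells (Fisher's exact test, p = 0.0830, Benjamini-Hochberg adjusted p = 0.979 over 36 tests). Onecut2 and Spdef, a transcription factor of mucous cells, had a lost region (Fisher's exact test, adjusted p = 1), and Onecut2 had 0 when 50% of the narrower peak had to overlap. The gained region at Hnf4a, 350 bp on chromosome 2 from 163580307 to 163580656, lay 7400 bp beyond the gene, and that at Atp4a, 391 bp on chromosome 7 from 30707555 to 30707945, lay 4264 bp from it. Gastric genes with a gained region were 0 of 19 within 2 kb of gene ends, 1 of 25 by nearest gene and 2 of 26 with equal numbers of peaks. Those with a lost region were 1, 2 and 1 in the same order. Leaving out single libraries gave 3 to 10 gastric genes with a gained and 4 to 8 with a lost region, of 25 to 27. Of 98 regions at gastric loci, 67 were called in each KrasLA1 tumour, 77 in KrasLA1;Dicer1S2D replicate 1 and 52 in KrasLA1;Dicer1S2D replicate 2. In the tumours of replicate 1 alone, 8 of the 27 genes had such a shared region (Fisher's exact test, p = 0.0507, adjusted p = 0.913). The intestinal list (12 genes with a region) and the liver and pancreas list (10 genes) had 0 genes with a gained or lost region. With equal numbers of peaks each of these lists had 1 gene with a gained region, and the liver and pancreas list had 2 of 9 with each region given to its nearest gene (Fisher's exact test, p = 0.0150, adjusted p = 0.242) and 3 of 8 without KrasLA1 replicate 1 (Fisher's exact test, p = 0.00983, adjusted p = 0.118).

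At loci of alveolar cells, 5 genes had a lost and 1 a gained region, and neither alveolar list passed the test. Among all 15882 genes with a region, 4.87% had a lost and 1.78% a gained region, without matching for the number of regions per gene. Of 11 genes of alveolar type 1 cells, the flat cells of gas exchange, 3 had a lost region: Ager, a receptor of their membrane, Aqp5, a water channel, and Akap5 (Fisher's exact test, p = 0.0141, adjusted p = 0.509). The region at Aqp5 lay within the gene (chromosome 15, 99592048 to 99592573), as did that at Akap5 (chromosome 12, 76324733 to 76325067), and that at Ager lay 5033 bp outside (chromosome 17, 34591648 to 34592427). Clic5 had a gained region (adjusted p = 0.979, Fisher's exact test). With equal numbers of peaks 1 type 1 gene had a lost and 1 a gained region (Fisher's exact test, p = 0.341 for lost), and Ager had 0 lost regions when 50% of the narrower peak had to overlap. Within 2 kb of gene ends 2 of 11 had a lost region (Fisher's exact test, p = 0.00999, adjusted p = 0.331). By nearest gene it was 3 of 12 (Fisher's exact test, p = 0.0202, adjusted p = 0.242). With single libraries left out, 3 to 7 of 11 type 1 genes had a lost and 1 to 3 a gained region. Of 18 genes of surfactant-producing alveolar type 2 cells, 2 had a lost region, Nkx2-1 and Slc34a2, a phosphate transporter, and 0 had a gained region (Fisher's exact test, adjusted p = 0.979 for lost). Without KrasLA1 replicate 2, 8 of the 18 type 2 genes had a gained region (Fisher's exact test, p = 0.00111, adjusted p = 0.0400), the opposite direction; its adjusted p was 0.948 or 1 under the other settings tried. In the direction of loss the count was 9 of 18 without KrasLA1 replicate 1 (Fisher's exact test, adjusted p = 0.168) and 6 of 18 without KrasLA1;Dicer1S2D replicate 2 (Fisher's exact test, adjusted p = 0.114), and the adjusted p was 0.114 to 1 over all settings. KrasLA1 replicate 2 had the most regions at type 2 loci, 93 of 102, against 61 in KrasLA1 replicate 1, 80 in KrasLA1;Dicer1S2D replicate 1 and 63 in KrasLA1;Dicer1S2D replicate 2.

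Loci of other cells of the lung were examined in the same way. Of 6 endothelial genes, Flt1, a receptor of vascular growth factor, and Tek, the angiopoietin receptor, had a lost region (Fisher's exact test, p = 0.0311, adjusted p = 0.561). Acta2, the actin of smooth muscle, had 2 lost regions and was the 1 of 6 fibroblast and smooth muscle genes with any. Spi1, a transcription factor of myeloid cells, was the 1 of 11 myeloid genes. Of 12 airway genes, the mucin gene Muc5b had a gained region and Trp63, a transcription factor of basal cells, a lost one. Of 12 genes of epithelial-mesenchymal transition, the cadherin gene Cdh1 and its repressor Zeb1 had a lost region. Fisher's exact test gave an adjusted p of 0.979 or 1 for the fibroblast, myeloid, airway and transition lists. Lymphocyte (7 genes) and neuroendocrine (5 genes) loci had 0 gained and 0 lost regions. These counts changed with the setting. By nearest gene 3 of 12 transition genes had a lost region (Fisher's exact test, p = 0.0202, adjusted p = 0.242). Leaving out single libraries gave 2 to 4 endothelial genes with a lost and 0 to 1 with a gained region. For fibroblast and smooth muscle genes it gave 1 to 3 and 0 to 4, and for neuroendocrine genes 0 to 3 and 0 to 1, in the same order.

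**Figure D3:**
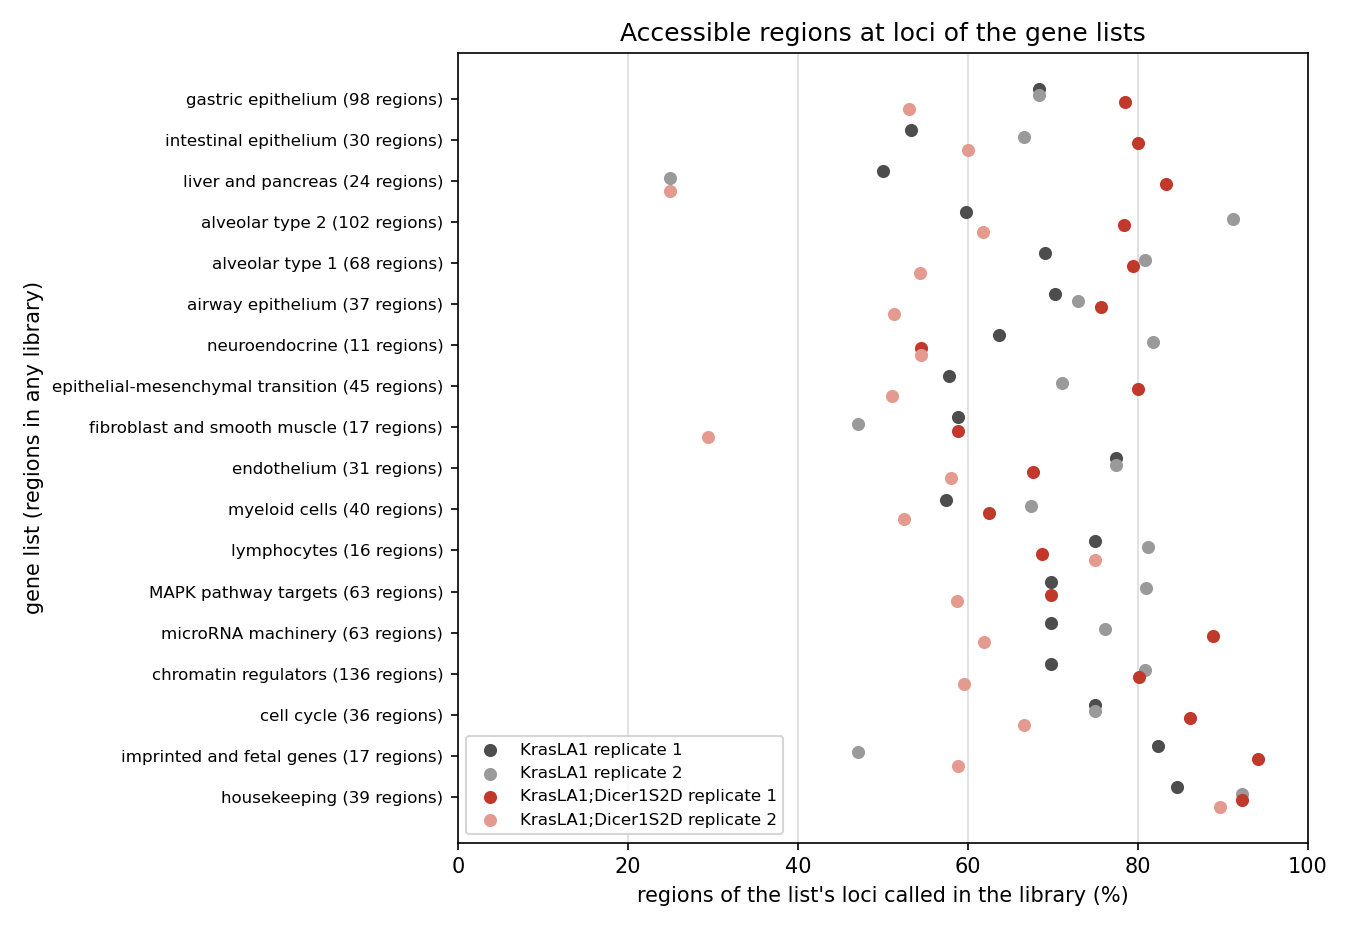
Share of regions at the loci of each gene list that was called in each library (%), one point per library. KrasLA1;Dicer1S2D replicate 2, the library with the fewest peaks, had 52 of 98 regions at gastric loci and 35 of 39 at housekeeping loci.

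Targets of the MAPK pathway were open in all tumours, and 15 of 15 had a peak within 2 kb of a gene end in every library. Spry1 and Spry2, feedback inhibitors of the pathway, had 2 lost regions each and were the only members of this list with a gained or lost region (Fisher's exact test, adjusted p = 0.979). By nearest gene 3 of 15 had a lost region (Fisher's exact test, p = 0.0373, adjusted p = 0.335). Within 2 kb of gene ends it was 2 of 15 (Fisher's exact test, p = 0.0184, adjusted p = 0.331). With single libraries left out, 3 to 8 of 15 had a lost region. Of 21 chromatin regulators, Chd4, an ATPase of a nucleosome remodelling complex, had a lost region (Fisher's exact test, adjusted p = 1). Chd4 had 0 with equal numbers of peaks, and the list had 0 with each region given to its nearest gene. With single libraries left out, 2 to 9 of the 21 regulators had a lost region. MicroRNA machinery (13 genes), cell cycle (12), imprinted and fetal (6) and housekeeping genes (14) had 0 gained and 0 lost regions on the autosomes. With equal numbers of peaks 1 gene of the microRNA machinery had a gained region. With single libraries left out, 0 to 4 of 13 microRNA machinery genes had a gained and 0 to 5 a lost region. Without KrasLA1 replicate 1, 3 of 6 imprinted and fetal genes had a gained region. All 16 housekeeping genes, X included, had a peak in each library.

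With equal numbers of peaks, the gained region of Muc5b and the lost regions of Onecut2, Spdef, Slc34a2, Aqp5, Akap5, Trp63, Zeb1, Tek, Flt1, Spi1, Spry1 and Chd4 were no longer called as such, and those of the other list genes named here were. In that setting 1 airway gene still had a gained region, and 1 gastric, 2 alveolar type 2 and 2 MAPK genes a lost one. Genes not named here had therefore entered these lists in place of some that dropped out. Over the 18 lists and both directions, 0 of 36 tests had an adjusted p under 0.05, and 2 had an unadjusted Fisher's exact p under 0.05. The replicate-number split gave 0 and 1, and the crossed split 0 and 2, in the same order. Neighbouring genes and regions are not independent replicates, and these tests describe the 4 libraries. The tests did not match genes by their number of regions, and a gene with many regions has more chances of a gained or lost one. Loci of the 12 alveolar type 1 genes held 68 regions, and those of the 18 type 2 genes 102. Random lists in the simulation were not matched either, so they cannot show such a bias.

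At Dicer1 itself, 4 and 3 of 6 regions were called in KrasLA1 replicates 1 and 2, and 6 and 3 in KrasLA1;Dicer1S2D replicates 1 and 2, with 0 gained and 0 lost. Nkx2-1, the transcription factor that maintains lung epithelial identity, had 2 regions called in all 4 tumours: 1 of 2813 bp overlapping the gene (chromosome 12, 56534883 to 56537695) and 1 of 1214 bp beside it (56529123 to 56530336). Its lost region measured 343 bp (56525423 to 56525765) and lay beside a region of 259 bp (56526332 to 56526590) called in KrasLA1;Dicer1S2D replicate 1 alone. At Hnf4a, 4 of 6 regions were called in KrasLA1 replicate 1, 1 in KrasLA1 replicate 2, 5 in KrasLA1;Dicer1S2D replicate 1 and 4 in KrasLA1;Dicer1S2D replicate 2. The region of 1127 bp at an end of Hnf4a (chromosome 2, 163506482 to 163507608) was called in both female and neither male tumour. Foxa2, a transcription factor of foregut epithelium, had 3 regions, all called in all 4 tumours. Gata6 had 3 regions, of which 2 were called in all 4 and 1 in KrasLA1 replicate 2 alone.

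Gained regions lay away from genes more often than lost regions. Of gained regions, 13.8% (95% Wilson interval 10.6 to 17.7) lay within 2 kb of an end of a protein-coding gene, against 19.2% (16.7 to 21.9) of lost regions (Fisher's exact test, adjusted p = 0.0350 over 4 classes). A further 39.2% of gained and 46.3% of lost regions lay inside genes (Fisher's exact test, adjusted p = 0.0350), and 12.7% and 9.87% lay outside within 10 kb (Fisher's exact test, adjusted p = 0.156). The rest, 34.3% (29.6 to 39.3) of gained and 24.6% (21.9 to 27.6) of lost regions, lay farther away (Fisher's exact test, adjusted p = 0.00297). Without KrasLA1 replicate 2 the order at gene ends was reversed, with 15.3% of gained and 13.5% of lost regions. Of regions called in all 4 tumours 40.8% (40.2 to 41.4) lay at gene ends, and of regions called in 1 library 12.1% (11.6 to 12.6). The splits without a contrast of genotypes showed a gap as well: 37.8% of regions of both female tumours only lay farther than 10 kb from genes against 25.4% of both male tumours only, and 38.2% against 24.7% for the crossed pairs. At gene ends these shares were 9.51% and 14.4%, and 13.1% and 13.8%.

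The second question was whether tumours of 1 genotype resembled each other. The Jaccard index, the share of base pairs in peaks of either library that both share, was 0.557 for the KrasLA1 tumours and 0.574 for the KrasLA1;Dicer1S2D tumours. The mean was 0.565 ± 0.0126 (SD, 2 pairs) within a genotype and 0.597 ± 0.0146 (SD, 4 pairs) between genotypes, a difference of -0.0320. Tumours of the same replicate number had a mean of 0.608 and crossed pairs 0.587, so 3 of the 3 splits had a mean at least as high as that of genotype (exact permutation over splits, one-sided p = 1). Without KrasLA1 replicate 1 the difference was -0.0157.

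Peak width was compared as well, at the 24604 autosomal regions with 1 peak in each library, since the files hold no other value per region. With limma on log2 width, 0 regions passed an adjusted p of 0.05 between genotypes, and 716 had an unadjusted p under 0.05, where chance gives 1230. Between replicate numbers the counts were 0 and 2147, and for the crossed split 0 and 1151. In simulated libraries whose spread varied between regions as in these, this test recovered 0 of 200 regions made 4 times wider, so the count of 0 does not exclude changes in width.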

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

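The test on sex was chosen only after its result was seen, and those on peak numbers, weak regions, cell types and chromosomes before.

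The difference between genotypes had opposite signs in the female and the male pair for several measures, each pair being 1 tumour against 1, and the difference between sexes was not tested. In the female pair KrasLA1;Dicer1S2D had 8661 more peaks than KrasLA1 and 2.27 Mb more covered sequence, and in the male pair the differences were -9887 peaks and -8.88 Mb. Regions at the loci of 11 of the 18 gene lists followed, with more in the female and fewer in the male KrasLA1;Dicer1S2D tumour. For epithelial lists the differences in regions called were 10 and -15 at gastric loci (female pair, then male pair), 8 and -2 at intestinal, 19 and -30 at alveolar type 2, 7 and -18 at alveolar type 1, 2 and -8 at airway, and 10 and -9 at epithelial-mesenchymal transition loci. At myeloid loci they were 2 and -6. At microRNA machinery loci they were 12 and -9, at chromatin regulators 14 and -29, at cell cycle genes 4 and -3, and at housekeeping genes 3 and -1. The total number of peaks moved the same way in each pair.

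More regions followed the replicate number than the genotype (53.7% against 12.1% of those called in 2 of 4 libraries). With equal numbers of widest peaks the genotype share was 16.0% (95% interval 15.2 to 16.8), under an even share of 33.3%. This argues against unequal peak numbers as the whole cause. It does not reach unequal depth or thresholds, since width only stood in for a score. Among the regions wider than 373 bp, their median, the replicate-number share was 56.0% (54.7 to 57.4). Weak peaks are not excluded by this, because 373 bp lies below the median of 789.5 bp for regions called in all 4 libraries. A few chromosomes with another copy number are argued against too, since the replicate-number share was higher than the genotype share on 19 of 19 autosomes, at 42.9% to 62.8% against 5.86% to 18.2%. Other cell types cannot be told apart from the tumour cells, because only 20 such regions lay at stromal and immune loci (odds ratio 0.973, 95% interval 0.363 to 2.61). Sex and any shared handling of same-numbered samples remain open, as they form the same split; on X that split held 39.2% (33.2 to 45.6) of the regions called in 2 libraries.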

How the results depend on the processing

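The alternatives for gene assignment, peak width, the shares of splits, and libraries left out of the gene lists, similarity and annotation were chosen after seeing the data. The test of differential regions and its alternatives were not run, for lack of a value per region, nor were assignments by transcription start site, for lack of strand. Depth is unknown, so how far it limits the calls was not tested.

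Gained and lost counts stayed within 1.5 times under the other overlaps, the widest 75% of peaks, X and Y included and the width minimum. Equal numbers of peaks gave 569 gained regions. The genotype share was 13.5% with the widest 75% of peaks and 16.0% with equal numbers, and the replicate-number share 52.2% and 57.9%; the order of the splits held. Leaving out each library gave 1092 to 7558 gained and 1577 to 6291 lost regions, because fewer libraries then have to hold or to lack the peak. It gave a difference in peak number of -8370.5 to 7144.5, reversed without KrasLA1 replicate 2 (903.5) and without KrasLA1;Dicer1S2D replicate 2 (7144.5), the library with the fewest peaks. The difference in Jaccard index ranged from -0.0417 to -0.0157, and the tests of gene lists past the threshold from 0 to 1. That 1 test was the gain at alveolar type 2 loci without KrasLA1 replicate 2. With all libraries 0 of 18 type 2 genes had a gained region, so the regions behind this call had a peak in the library left out. Why that library had the most regions at these loci was not tested. With 5 kb around gene ends, 23.2% of gained and 28.6% of lost regions lay there, as a wider window must give; without single libraries it was 10.3% to 15.3% and 13.5% to 20.5%, and without KrasLA1 replicate 2 the order of the classes was reversed (15.3% and 13.5%); the cause was not tested.

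With a replicate block in the limma model of peak width, 0 regions passed, as without it (1093 against 716 at an unadjusted p under 0.05). The deviations of same-numbered libraries correlated at 0.122, which is 1 value, since groups of 2 give the same for both pairs. It decides nothing, and with 2 pairs the numbers were not taken as pairing. The gained and lost regions are already those that differ the same way in both same-numbered pairs.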

Other observations

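The genes named in the next paragraph were chosen after their values were seen, and the lists were fixed before. The tests on chromosomes were not among the planned ones, though what each should show was set down before its result was seen.

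Of 18 alveolar type 2 genes, 8 (Abca3, a lipid transporter of surfactant, Foxa1, Lpcat1, Lyz1, Muc1, Nkx2-1, Sfta2 and Slc34a2) had a region called in KrasLA1 replicate 2 and KrasLA1;Dicer1S2D replicate 1 alone (Fisher's exact test, p = 0.00254, adjusted p = 0.0915). These are the libraries with the most peaks (44654 and 50282), and 2352 of the 15864 other genes had such a region. In the tumours of replicate 1 alone, 8 of 27 gastric genes had a region: Agr2, Capn8, Capn9, Ghrl (ghrelin), Gkn2, Gkn3, Hnf4a and Onecut2 (Fisher's exact test, adjusted p = 0.913). At liver and pancreas loci, 20 of 24 regions were called in KrasLA1;Dicer1S2D replicate 1, 12 in KrasLA1 replicate 1 and 6 in each male tumour. Nr5a2 alone held 9 of these regions. Of the 9, KrasLA1;Dicer1S2D replicate 1 had 8, KrasLA1 replicate 1 had 2, KrasLA1 replicate 2 had 1 and KrasLA1;Dicer1S2D replicate 2 had 0. Neither Fisher's test passed the adjusted threshold, and the counts of regions at liver and pancreas loci were not tested.

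The share of regions called, among those called in at least 1 other library, differed between chromosomes from tumour to tumour. It was highest on chromosome 16 in KrasLA1 replicate 1 (70.4%, against 63.9% over all autosomes), 11 in KrasLA1 replicate 2 (76.9% against 69.0%), 17 in KrasLA1;Dicer1S2D replicate 1 (81.3% against 75.9%) and 7 in KrasLA1;Dicer1S2D replicate 2 (62.5% against 54.3%). It was lowest on chromosome 17 (55.2%), 10 (62.2%), 18 (70.4%) and 13 (47.7%), in the same order. The 2 male tumours, of different genotypes, shared much of this pattern. In KrasLA1 replicate 2 and KrasLA1;Dicer1S2D replicate 2 the share deviated by 5.88 and 4.69 percentage points on chromosome 5. The values were 3.85 and 8.21 on 7, -6.87 and -5.11 on 10, -5.10 and -6.62 on 13 and -5.54 and -3.78 on 14. Their signs differed on chromosomes 9 (2.84 and -1.05), 17 (0.970 and -0.0674) and 18 (0.568 and -0.885). In KrasLA1;Dicer1S2D replicate 1 the deviation was 0.0233 on chromosome 5, -2.99 on 7, 3.01 on 10, 4.38 on 13 and 4.58 on 14. Except on chromosome 5, these were opposite in sign to those of the male tumours. Each share was taken among regions called in the other libraries, so the likeness of the male tumours is not independent of this library.

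A hypothesis is that whole chromosomes differ in copy number between the tumours, which would move both ends of a chromosome together. Over the 19 autosomes, the deviations of the outer parts of a chromosome, the first and the last of 3 equal parts, correlated in 4 of 4 libraries (Pearson r 0.582 to 0.667, Spearman rho 0.570 to 0.726, largest permutation p 0.00801 and 0.0124, largest adjusted p 0.0107 over 12 tests), and r was 0.580 to 0.693 without the 2 most extreme chromosomes. A trend with gene density is argued against as the whole cause, since after its removal the correlation of the outer parts held in 4 of 4 libraries (r 0.653 to 0.874). Whole-chromosome copy number may account for the pattern, but among regions called in all 3 other libraries only KrasLA1;Dicer1S2D replicate 2 was under 0.05 by both coefficients (permutation p = 0.00366 for Pearson, 0.011 for Spearman), and KrasLA1 replicate 1 by Pearson alone (0.0372 against 0.0982). The libraries are not independent here, since each share was taken among regions called in the others. The 4 of 4 libraries are therefore not 4 separate results. A gain or loss in 1 tumour also changes which regions enter the shares of the others. The pattern shared by the male tumours therefore does not decide whether copy number changes arose separately in each tumour. An effect of replicate number, sex or handling on this pattern was not tested. GC content was not tested without a genome, chromosomes are not independent replicates, and no biological explanation from the groups was tested.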
